A study of Mus musculus with 8 samples.

How the data were processed

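RNA sequencing was done, per the labels, on primary cardiac fibroblasts from hearts of wild-type mice, cultured for 3 days, at 4 ages with 2 libraries each. The labels name polyA RNA as the molecule, while the protocol names an rRNA depletion kit followed by a stranded mRNA library kit, so the RNA selection is uncertain. Sequencing was paired-end on an Illumina HiSeq X instrument. The processing notes name Trimmomatic 0.36 for trimming, featureCounts of Subread 1.5.1, SAMtools and the build mm10. The aligner, the annotation release and the strand setting are not given in the sources used here.

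The deposited table holds 56691 genes with raw counts, FPKM and the exonic gene length of each gene. The raw counts per gene and library, as deposited by the authors, are whole numbers, and every test below was made on them. The FPKM values of the authors equal the count scaled by exonic gene length and by the library's total, to within 0.005, with no scaling between libraries, and entered no test. The exonic gene length in the deposited table (an other unit, in bases) was used only in that check. Of these genes 25966 had no count in any library, and 2639 had no symbol and took 0.073 to 0.205% of a library's counts. The gene coordinates in the table match those of GRCm38 in GENCODE M21 at both ends for 1472 of 52073 shared identifiers, so the only position printed, that of Nr4a3, comes from GENCODE M21.

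Library totals ran from 17283764 to 22311330 counts. A gene with no count in a group was set at a floor of 3 counts over the group's 2 libraries, and its change is given as a lower bound. Genes with 1 to 3 counts in a group are given as count ratios with a 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where a list held genes with no count, its median was computed also with those genes at their bound, and no median printed in the report differed.

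Genes were kept by filterByExpr of edgeR on age group (minimum count 10, minimum total count 15), which left 16466. The libraries were scaled by TMM, and all 8 were fitted together with 1 coefficient per age in edgeR 4.0.16 by quasi-likelihood F tests, which leaves 4 residual degrees of freedom, with 24.2 prior degrees of freedom and a common biological coefficient of variation of 0.0364. The 6 pairwise comparisons and the test of any difference among the ages were each adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p of 0.05. The SE of a log2 fold change comes from the same fit. Levels are TMM-scaled CPM, and principal components used log2 CPM with a prior count of 2. A replicate chi-square per degree of freedom was computed over genes with a summed count of at least 20.

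Gene lists were tested with camera of limma 3.58.1 on the same fit, with a preset correlation of 0.01 between genes and Benjamini-Hochberg over the 39 lists with at least 3 tested genes. Camera asks whether a list moved against all other genes. The test was repeated with the correlation estimated from the data, and fry asked whether each list moved by itself. In the estimated form 14, 16 and 15 lists had an unadjusted p under 0.05 for 3, 12 and 24 months against neonatal, and 12 for 24 against 3 months. Of the lists without a set test, the lymphocyte markers had 1 tested gene and the erythroid genes 0, and the 4 Y-linked genes served as a check of the libraries' sex. The age groups, the 6 comparisons, the gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

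Genes named in the report follow that rule. For 3 months against neonatal, 24 months against neonatal and 24 against 3 months it takes the 10 largest positive and the 10 largest negative log2 fold changes, and for the other 3 comparisons the 5 and 5, among called genes with a mean of at least 5 CPM, no overlap between the libraries of the groups, and a symbol that is not a predicted or clone-based name. It adds 17 focus genes, from the NR4A receptors, senescence, reprogramming, matrix and inflammation, and up to 4 members of each list with the smallest p. Xist and the genes of the closing section on glutathione were singled out after their values were seen where the rule did not take them.

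Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter (10 CPM in at least 2 libraries), a replicate block, only the 4 libraries compared, each library left out in turn, and a minimum change of 2-fold. With 1 library left out, the remaining library of that age is assumed to vary like the other ages. Autosomal genes only, and the neonatal or the 24-month libraries left out, were added after the data were examined. The median log2 fold change of the 62 lists described was also computed under the 3 scalings, and 1 changed sign, that of the non-collagen matrix genes at 3 months against neonatal (0.07, 0.05 and -0.01).

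Enrichment used the biological process terms in the deposited table, with 2089 terms of 10 to 200 genes among 12870 annotated genes that were tested, for genes called with at least 2-fold change, by a one-sided hypergeometric test with Benjamini-Hochberg. The procedure was tested on simulated data built from the libraries' own means and spread. In the simulation of 3 months against neonatal it called 77.6% of genes changed 1.5-fold, 97% of those changed 2-fold and 6 of 16236 unchanged genes. In that of 24 against 3 months it called 76.1% and 89.6%, and 10 of 16236 unchanged genes. A planted list was called with the preset correlation (adjusted p = 1.16e-52 and 4.18e-92) and with the estimated one (adjusted p = 0.00235 and 0.001), and 0 of 38 unchanged lists were. The simulated genes varied independently of each other, so these runs do not test list calls where genes are correlated. Beside the planted list, only 67, 67 and 66 of 16466 genes were changed, 1.5-fold, 2-fold and 4-fold, none from the lowest levels. The runs therefore do not test calls or scaling where many genes change, as the 52.4% called between neonatal and 3 months. Computations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.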

Results

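Gene expression was measured by RNA sequencing in primary cardiac fibroblasts, the matrix-producing connective-tissue cells of the heart, taken from wild-type mice of 4 ages and cultured for 3 days. The groups were neonatal pups (postnatal days 1 to 3) and mice of 3, 12 and 24 months, with 2 libraries each, 8 in all. The series addresses why fibroblasts of adult and aged hearts are harder to convert directly into cardiomyocyte-like cells, and its title names the nuclear receptor gene Nr4a3 and cellular senescence. Library totals were 21046675 and 17336346 counts for the neonatal libraries, 22311330 and 21026804 at 3 months, 17283764 and 19940912 at 12 months, and 21700917 and 21555853 at 24 months. Between 22483 and 23638 genes had at least 1 count per library, and 16466 passed the filter on low counts and were tested. Levels are given as normalised read counts scaled to library size (CPM), mean ± SD with n = 2 libraries per age, and changes as log2 fold changes ± SE. Genes given as leading or largest in a comparison are so among called genes with a mean of at least 5 CPM over the 8 libraries and no overlap between the groups. The labels do not say that the replicates came from separate animals or cultures, so the p-values measure only the spread between these samples.

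The 4 ages were well separated, and neonatal fibroblasts stood farthest apart. The first principal component carried 76.4% of the variance and placed the neonatal libraries at -110.3 and -110.2 and the adult libraries between 27.8 and 44.8. The second (8.8%) separated 3 months, at -32.6 and -34.5, from 12 months, at 26 and 27.8, and the third (5.4%) set the 24-month libraries apart at 25.6 and 27.8. Chi-square per degree of freedom between libraries was 2.44 to 2.89 within an age and 17.2 to 228 between ages. In the test of any difference among the 4 ages, 10537 of 16466 genes (64.0%) passed at an adjusted p of 0.05. Of these, 4203 had their highest mean in neonatal cells, 1944 at 3 months, 2297 at 12 months and 2093 at 24 months. Ordered by their 4 group means alone, with no test of each step, 906 of these genes had means rising and 800 means falling with age throughout, together 16.2% of the 10537.

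**Figure D1:**
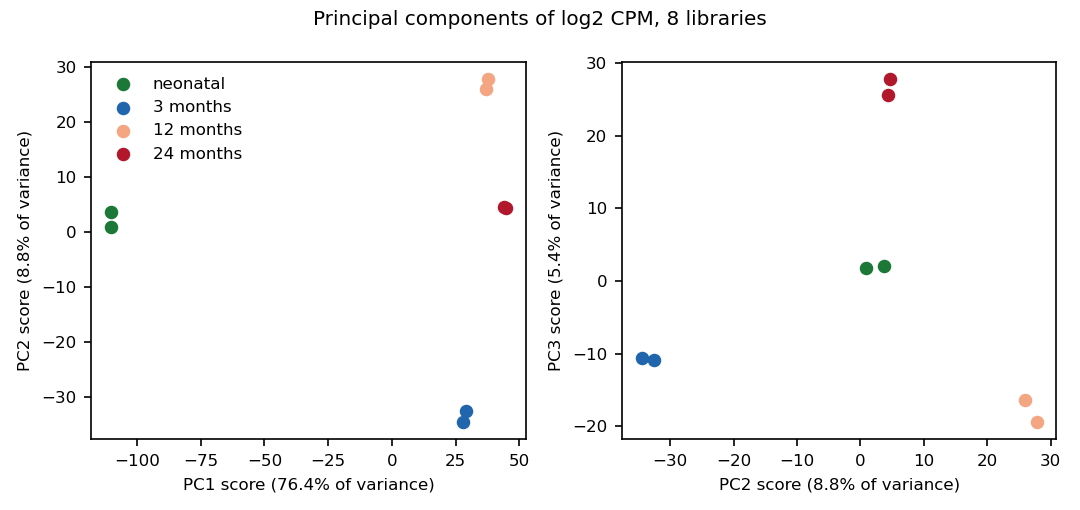
Principal component scores of the 8 libraries, computed on log2 CPM; each point is 1 library, coloured by age, with PC1 against PC2 on the left and PC2 against PC3 on the right. Neonatal libraries lie near -110 on PC1, and the 3 adult ages separate on PC2 and PC3.

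Sex-linked transcripts differed between the ages. Xist, the RNA that silences an X chromosome in female cells, was at 1280 and 1290 CPM in the neonatal libraries and at 775 and 833 CPM at 24 months. It was at 0.45 and 0.479 CPM at 3 months and 0.286 and 0.448 CPM at 12 months. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a median of 20.2% of their 3-month level in neonatal cells (range 15 to 21.9%), 97.5% at 12 months (90.7 to 105%) and 30.6% at 24 months (25.2 to 31.5%). Neonatal and 24-month libraries therefore held both female and male transcripts, while Xist stayed below 1 CPM at 3 and 12 months. X-linked genes made up 3.33 to 4.11% of the genes called in the 6 comparisons and 3.33% of the genes tested.

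**Figure D2:**
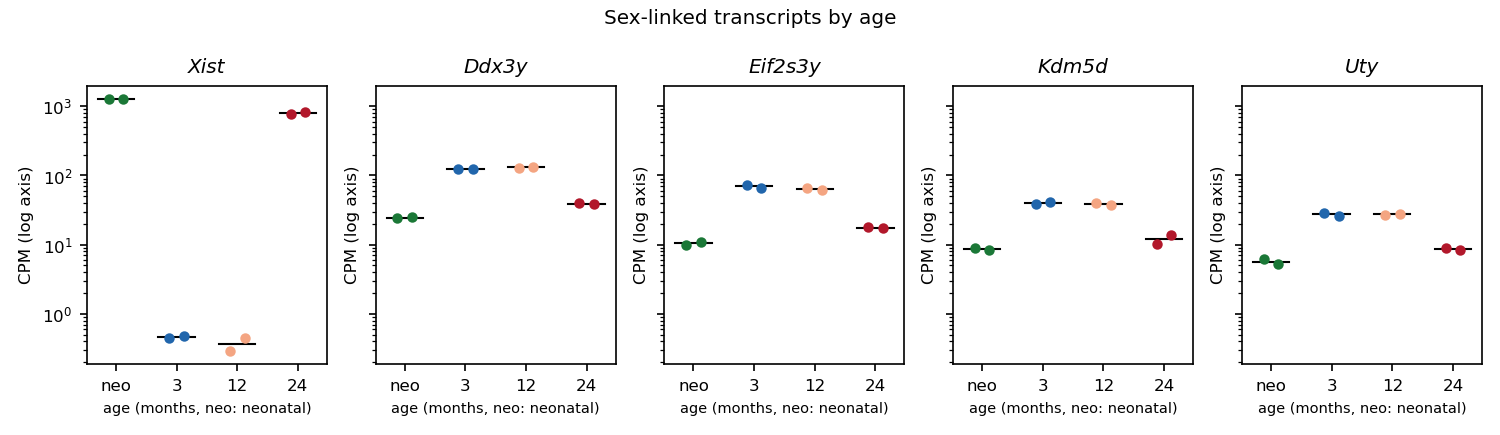
Level of Xist and of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in each library, in CPM on a shared log axis, by age; points are libraries and bars are means of 2. Xist is at 775 CPM or more in neonatal and 24-month libraries and below 1 CPM at 3 and 12 months, where the Y-linked genes are highest.

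How the NR4A nuclear receptors change with age was asked first, because the series centres on Nr4a3, an orphan nuclear receptor encoded by an immediate early gene. Nr4a3 (ENSMUSG00000028341, protein-coding, GRCm38 chromosome 4, 48045153 to 48086447, + strand) was lowest in neonatal fibroblasts and highest at 12 months. Its level was 1.19 ± 0.56 CPM in neonatal cells, 2.25 ± 0.19 at 3 months, 4.30 ± 0.81 at 12 months and 3.42 ± 0.14 at 24 months. It rose from neonatal to 3 months by 0.95 ± 0.30 (adjusted p = 0.00923), to 12 months by 1.89 ± 0.28 (adjusted p = 8.98e-07) and to 24 months by 1.55 ± 0.28 (adjusted p = 2.52e-05). From 3 to 12 months it rose by 0.94 ± 0.24 (adjusted p = 0.00308). The 24-month level did not pass the test against 3 months (0.60 ± 0.24, adjusted p = 0.0881) or against 12 months (-0.34 ± 0.22, adjusted p = 0.341). Nr4a1 and Nr4a2, its paralogs, went the other way early. Against neonatal, Nr4a1 fell at 3 months (-0.41 ± 0.10, adjusted p = 0.000644) and 12 months (-0.38 ± 0.10, adjusted p = 0.00138). At 24 months it was at -0.13 ± 0.09 (adjusted p = 0.247). Nr4a2 fell at 3 months (-0.68 ± 0.20, adjusted p = 0.00473), 12 months (-0.67 ± 0.20, adjusted p = 0.00603) and 24 months (-0.92 ± 0.20, adjusted p = 0.000315). Nr4a1, at 35.6 ± 1.4 CPM at 3 months, rose to 43.2 ± 8.9 CPM at 24 months (0.28 ± 0.10, adjusted p = 0.0432). Nr4a3 had few reads, 17 and 28 in the neonatal libraries, 53 and 44 at 3 months, 65 and 98 at 12 months and 75 and 70 at 24 months. Its rise from neonatal to 3 months did not pass without neonatal replicate 1 (0.47, adjusted p = 0.277), without 3-month replicate 1 (0.86, adjusted p = 0.0567) or with DESeq2 (0.92, adjusted p = 0.0688). It was 1.46 without neonatal replicate 2 (adjusted p = 0.00231, the lowest of all alternatives). Its rise from 3 to 12 months did not pass without 12-month replicate 2 (0.73, adjusted p = 0.0945) or with DESeq2 (0.94, adjusted p = 0.0506), with adjusted p from 0.000269 to 0.0945 over the alternatives.

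The changes of the paralogs also leaned on single libraries. The rise of Nr4a1 from 3 to 24 months failed the test in 11 of 17 alternatives (adjusted p from 3e-04 to 0.81). It was 0.05 without 24-month replicate 1 (adjusted p = 0.81), 0.24 without 3-month replicate 1 (adjusted p = 0.209), and 0.32 without 3-month replicate 2 (adjusted p = 0.0691). It was 0.28 without neonatal replicate 1 or 2 (adjusted p = 0.0513 and 0.0503), against 0.47 without 24-month replicate 2 (adjusted p = 3e-04). The fall of Nr4a2 at 3 months did not pass without neonatal replicate 1 (-0.58, adjusted p = 0.0617), without 3-month replicate 1 (-0.56, adjusted p = 0.0591) or with DESeq2 (-0.69, adjusted p = 0.069), with adjusted p from 0.00182 to 0.069 over the alternatives. Its fall at 12 months did not pass without neonatal replicate 1 (-0.57, adjusted p = 0.0682) or with DESeq2 (-0.68, adjusted p = 0.075), with 0.00333 its lowest. The fall of Nr4a1 at 12 months did not pass without 12-month replicate 1 (-0.25, adjusted p = 0.0649), with 1e-06 its lowest. At 24 months against neonatal Nr4a1 was at -0.38 without 24-month replicate 1 (adjusted p = 0.00128) and at 0.06 without 24-month replicate 2 (adjusted p = 0.601), the lowest and the highest of its alternatives.

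**Figure D3:**
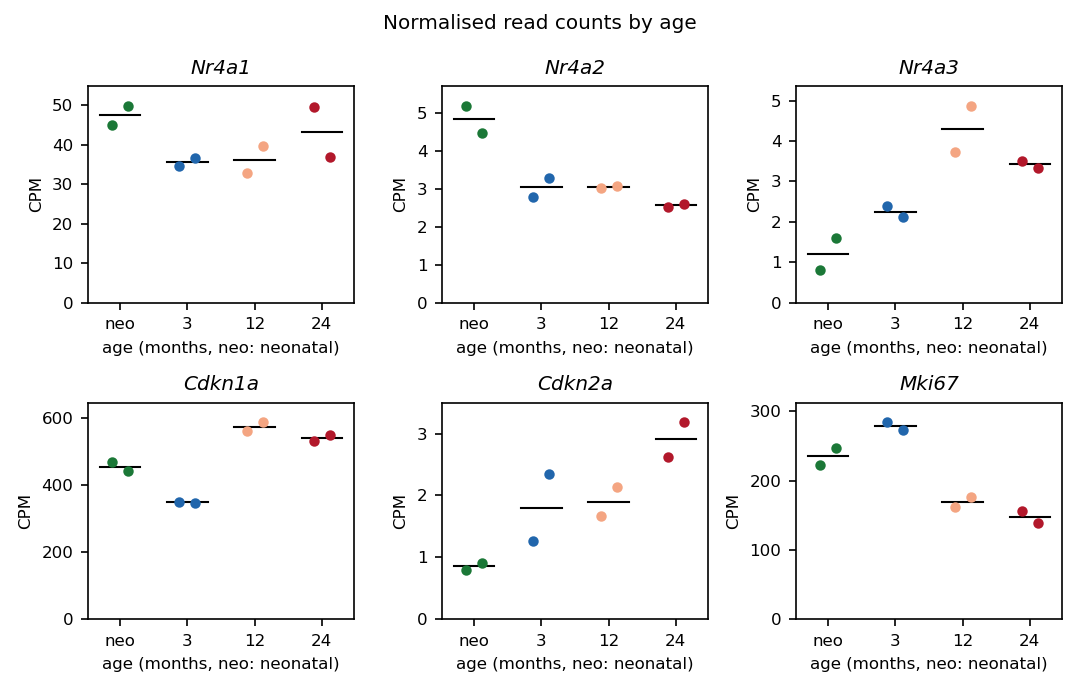
Level of Nr4a1, Nr4a2, Nr4a3, the cell-cycle inhibitor genes Cdkn1a and Cdkn2a, and the proliferation marker Mki67 in each library, in CPM on linear axes from 0, by age; points are libraries and bars are means of 2. Mean Nr4a3 is 1.19 CPM in neonatal and 4.30 CPM at 12 months, and mean Mki67 is 279 CPM at 3 months and 147 CPM at 24 months.

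The comparison of 3 months with neonatal asked how cardiac fibroblasts change as the heart matures. Many secreted inflammatory and innate defence genes rose steeply, while most imprinted genes, contractile genes and markers of other heart cells fell. Mmp3, a matrix-degrading protease, rose from 3.73 ± 0.11 to 3440 ± 94 CPM (9.85 ± 0.07, adjusted p = 4.38e-38). The neutrophil-attracting chemokine Cxcl5 rose from 1.53 ± 0.57 to 1350 ± 210 CPM (9.81 ± 0.14, adjusted p = 1.34e-30), and the central complement component C3 from 9.26 ± 1.3 to 1330 ± 9.7 CPM (7.18 ± 0.08). The eosinophil chemokine gene Ccl11 had no count in neonatal cells and was at least 87-fold higher. Other large rises were in the acute-phase genes Hp (8.08 ± 0.25) and Saa3 (7.37 ± 0.22), the nucleic-acid sensor Zbp1 (7.95 ± 0.14), complement genes C4b (7.55 ± 0.12) and C7 (7.46 ± 0.28) and the metalloreductase Steap4 (7.22 ± 0.19). Falls were led by Xist (-11.41 ± 0.09), mesothelial genes Lrrn4 (-8.90 ± 0.24) and Upk1b (-8.59 ± 0.24), and Msln, whose count ratio was 497 (95% counting interval 137 to 4110). They also included the atrial peptide gene Nppa (-8.42 ± 0.28), the imprinted growth regulator Dlk1 (-7.63 ± 0.20), Kank4 (-7.47 ± 0.16), Pkhd1l1 (-7.24 ± 0.22), and Gpm6a (-7.15 ± 0.25). Cardiac troponin T, Tnnt2, went from 764 ± 41 to 5.46 ± 0.54 CPM (-7.13 ± 0.08). In total 8621 genes passed, 4608 higher and 4013 lower at 3 months, and 3101 of them changed at least 2-fold (1525 higher, 1576 lower). With upper-quartile scaling the split turned to 3759 higher and 4974 lower, from 53.5% to 43.0% higher. Several large folds rest on few reads in the lower group. Hp had all 5 of its neonatal counts in replicate 2, and was at 6.95 without neonatal replicate 1 and at least 260-fold higher without neonatal replicate 2. Upk1b and Nppa had all 5 of their 3-month counts in replicate 1. They were at -7.67 and -7.50 without 3-month replicate 2, and at least 327-fold and 294-fold lower without 3-month replicate 1. Gpm6a was at -6.29 without 3-month replicate 1, and without replicate 2 had a count ratio of 677 (95% counting interval 121 to 26800). Lrrn4 had ratios of 327 (112 to 1590) without 3-month replicate 1 and 1050 (187 to 41300) without 3-month replicate 2. Without neonatal replicate 1, Saa3 was at 8.09 and C7 had a ratio of 417 (74.6 to 16500).

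By gene list, 25 of 39 lists moved against all other genes between neonatal and 3 months, 14 up and 11 down. Interferon response genes rose almost as a block: 37 of 38 were higher and 1 did not pass, with a median log2 fold change of 3.63 (adjusted p = 1.77e-61). Among them were the antiviral genes Oasl2 (3.84 ± 0.07), Isg15 (4.56 ± 0.10) and Gbp3 (4.70 ± 0.11). Of 40 senescence-associated secretory factors 29 rose and 10 fell (adjusted p = 2.68e-24), including the monocyte chemokines Ccl7 (4.06 ± 0.06) and Ccl2 (2.97 ± 0.05). Of 23 chemokines 18 rose and 2 fell (adjusted p = 1.31e-19). Resting fibroblast markers rose in 17 of 19 cases and fell in 2 (adjusted p = 6.24e-28), with the stem and progenitor antigen gene Ly6a at 7.18 ± 0.10, the fibroblast receptor Pdgfra at 2.87 ± 0.05 and Abca8a at 4.34 ± 0.05. Downward, 18 of 20 myofibroblast contractile genes fell and 2 rose (adjusted p = 2.69e-19), with smooth muscle actin Acta2 going from 4130 ± 140 to 1230 ± 77 CPM (-1.75 ± 0.04) and Tagln by -1.83 ± 0.05. Of 26 imprinted genes 22 fell and 3 rose (adjusted p = 5.95e-26). Beside Dlk1, these included H19 (-6.48 ± 0.09), Mest (-4.39 ± 0.08) and Plagl1 (-4.12 ± 0.07). Of 7 oncofetal genes 6 fell and none rose (adjusted p = 6.15e-12), including the chromatin protein Hmga2 (-4.70 ± 0.09) and the RNA-binding protein Igf2bp1 (-4.82 ± 0.14). All these counts were the same adjusted over the list alone. These 7 lists are those that also passed with an estimated correlation between genes. The secretory factor and chemokine lists share members such as Ccl2 and Ccl7, so their calls are not independent.

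Other lists moved with the preset correlation only. All 16 MHC class I genes rose (adjusted p = 6.8e-19, and adjusted p = 0.0571 with an estimated correlation), with H2-K1 at 2.36 ± 0.06. All 20 cholesterol synthesis genes also rose (adjusted p = 1.1e-11, and adjusted p = 0.06 with an estimated correlation), with the sterol enzyme Cyp51 at 1.34 ± 0.05. Of 20 complement genes 12 rose and 6 fell (adjusted p = 4.52e-13, and adjusted p = 0.0533 with an estimated correlation). Replication genes rose in 35 of 36 cases and fell in 1, by a median of 0.55 (adjusted p = 0.00136, and adjusted p = 0.543 with an estimated correlation). Mitosis genes rose in 29 of 38 cases and fell in 1 (adjusted p = 0.0435, and adjusted p = 0.742 with an estimated correlation), with the proliferation marker Mki67 at 0.25 ± 0.05. Of 23 p53 target genes 21 fell and 1 rose (adjusted p = 9.18e-06, and adjusted p = 0.173 with an estimated correlation), Cdkn1a, which encodes the cell-cycle inhibitor p21, by -0.38 ± 0.04. Of 28 collagens 16 fell and 9 rose (adjusted p = 1.67e-05, and adjusted p = 0.235 with an estimated correlation). The major fibrillar gene Col1a1 fell from 9580 ± 160 to 5290 ± 240 CPM (-0.86 ± 0.04), while Col3a1 rose from 4600 ± 46 to 13500 ± 160 CPM (1.55 ± 0.04). Non-collagen matrix genes went both ways, with 19 higher and 15 lower of 42 (16 lower adjusted over the list alone). Against all other genes the list was higher (adjusted p = 0.0026, and adjusted p = 0.38 with an estimated correlation), with a median of 0.07 that was -0.01 with upper-quartile scaling, and it did not pass with no filter on low counts (adjusted p = 0.095). Its lowest adjusted p over the alternatives was 9.85e-05. Among its members that fell, Fn1 went from 23200 ± 510 to 5710 ± 78 CPM and Postn from 2560 ± 37 to 231 ± 9.2 CPM (-3.47 ± 0.05). Among the cardiac transcription factors used in direct reprogramming, Gata4 (-0.70 ± 0.05), Mef2c (-0.82 ± 0.07) and Tbx5 (-1.03 ± 0.25) fell. All 22 cardiomyocyte markers fell too, so a change within fibroblasts was not separated from fewer transcripts of other cells. The counts of the other 7 lists named here did not change adjusted over the list alone. The mitosis list did not pass with the stricter filter (adjusted p = 0.171), without neonatal replicate 1 (adjusted p = 0.13) or without 3-month replicate 1 (adjusted p = 0.0678), with adjusted p from 1.94e-07 to 0.742 over the alternatives. Mki67 did not pass without neonatal replicate 1 (0.15, adjusted p = 0.0662, the highest of its alternatives) and Tbx5 not without 3-month replicate 2 (-0.63, adjusted p = 0.0509, also its highest), against -1.63 without 3-month replicate 1.

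Markers of other heart cells moved with these groups. All 22 cardiomyocyte markers fell (median -4.35, adjusted p = 2.7e-24, and adjusted p = 0.0696 with an estimated correlation), among them Myh6 (-5.37 ± 0.13, and -5.97 without 3-month replicate 2) and Actc1 (-6.66 ± 0.17). Endothelial markers fell in 14 of 18 cases and rose in 2 (adjusted p = 5.95e-19, and adjusted p = 0.0696 with an estimated correlation), with Ptprb going from 765 ± 32 to 61.8 ± 2.1 CPM. Epicardial and mesothelial markers fell in 11 of 12 cases and rose in 1 (adjusted p = 2.34e-07, and adjusted p = 0.0693 with an estimated correlation), the exception being Aldh1a2 (3.55 ± 0.05), which encodes a retinoic acid synthesising enzyme. Macrophage markers fell in 18 of 21 cases and rose in 2, by a median of -1.38 (adjusted p = 1.67e-05, and adjusted p = 0.225 with an estimated correlation). Adjusted over the list alone, 3 macrophage markers rose, and the other counts were the same. Falls of contractile and imprinted genes thus ran alongside lower cardiomyocyte, endothelial and mesothelial transcripts and a loss of Xist, whereas the rising interferon and chemokine genes moved opposite to the macrophage markers.

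Against neonatal, the 12-month and 24-month fibroblasts were asked whether the difference from birth persists at later ages. Largely the same kinds of genes led both comparisons. Both use the same 2 neonatal libraries, as does that of 3 months, so their likeness is not independent. Mmp3 was higher by 9.60 ± 0.07 at 12 months and 10.38 ± 0.07 at 24 months, Cxcl5 by 10.59 ± 0.13 and 10.42 ± 0.13, and Hp by 7.91 ± 0.26 and 9.23 ± 0.21. Ccl11 was at least 349-fold and 167-fold higher, and the chemokine gene Cxcl3 had count ratios of 371 (95% counting interval 102 to 3070) and 310 (85.6 to 2570). At 24 months the chemokine Cxcl14 (8.77 ± 0.16), Saa3 (8.52 ± 0.19), Zbp1 (7.93 ± 0.14) and C3 (7.88 ± 0.08) also rose, and the monocyte chemokine Ccl8 had a ratio of 306 (84.3 to 2530). Lower at 12 months were Xist (-11.73 ± 0.10) and the cartilage proteoglycan Acan, at least 364-fold, with count ratios of 1770 (317 to 69800) for Lrrn4, 867 (155 to 34300) for Msln and 707 (242 to 3430) for Dlk1. Lower at 24 months were Nrk (-8.93 ± 0.15), a kinase gene of fetal tissue, Slc38a4 (-7.70 ± 0.18), Dlk1 (-8.17 ± 0.21), Lrrn4 (-7.75 ± 0.21), Kank4 (-7.55 ± 0.17) and Sprr1a (-7.75 ± 0.30), and Upk1b at least 663-fold. Count ratios were 1020 (183 to 40400) for the laminin gene Lamc3, 978 (175 to 38700) for Msln and 467 (159 to 2270) for Gap43, a growth-cone protein. The inhibitor gene Cdkn2a, which encodes p16 and p19Arf and marks senescent cells, rose from 0.853 ± 0.079 to 1.90 ± 0.34 CPM at 12 months (1.17 ± 0.35, adjusted p = 0.00622). At 24 months it was at 2.91 ± 0.39 CPM (1.77 ± 0.33, adjusted p = 3.03e-05). The rise of Cdkn2a at 12 months did not pass without neonatal replicate 1 (1.05, adjusted p = 0.0612), without 12-month replicate 2 (0.97, adjusted p = 0.0769) or with DESeq2 (1.14, adjusted p = 0.0535). Its adjusted p ran from 0.00172 to 0.0769 over the alternatives. Without neonatal replicate 1, Hp was higher by 6.78 at 12 months and 8.11 at 24 months, and Saa3 by 9.24 at 24 months. Cxcl3 had ratios of 168 (46.3 to 1390) and 140 (38.7 to 1160) without neonatal replicate 1. Without neonatal replicate 2, Hp was at least 229-fold and 576-fold higher, and Cxcl3 at least 136-fold and 113-fold. Without 12-month replicate 1, ratios at 12 months were 464 (83 to 18300) for Msln and 378 (129 to 1840) for Dlk1, and Lrrn4 was at least 315-fold lower. Without 12-month replicate 2, the ratio of Lrrn4 was 821 (147 to 32400), and Msln and Dlk1 were at least 134-fold and 328-fold lower. At 24 months, Lamc3 had a ratio of 507 (90.8 to 20100) without 24-month replicate 1, and Msln and Gap43 were at least 162-fold and 232-fold lower. Without 24-month replicate 2, ratios were 602 (166 to 4970) for Dlk1, 492 (88.1 to 19500) for Msln and 235 (80.2 to 1140) for Gap43, and Lamc3 was at least 171-fold lower.

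At 12 months 9090 genes differed from neonatal, 4893 higher and 4197 lower, and at 24 months 8954 did, 4588 higher and 4366 lower. Changes of at least 2-fold numbered 3296 (1547 higher, 1749 lower) and 3375 (1718 higher, 1657 lower). With upper-quartile scaling the splits were 4322 higher and 4621 lower at 12 months, and 3925 higher and 5154 lower at 24 months. Of 39 lists 25 moved at each age, 13 up and 12 down. An estimated correlation left 6 at 12 months and 8 at 24 months. Senescence-associated secretory factors rose in 24 and fell in 9 of 40 cases at 12 months (adjusted p = 9.07e-27), and rose in 29 and fell in 8 at 24 months (adjusted p = 2.71e-31). Imprinted genes fell in 21 and rose in 3 of 26 cases at both ages (adjusted p = 4.34e-28 and 4.01e-27). Mitosis genes fell in 22 and rose in 1 of 38 cases at 12 months (adjusted p = 0.0263, and adjusted p = 0.827 with an estimated correlation). They fell in 32 with none higher at 24 months (adjusted p = 0.00068, and adjusted p = 0.625 with an estimated correlation). Adjusted over the list alone, 26 secretory factors rose and 10 fell at 12 months, and 22 imprinted genes fell at 12 months; the other counts did not change. The mitosis list at 12 months did not pass without neonatal replicate 2 (adjusted p = 0.0905), with adjusted p from 2.74e-06 to 0.827 over the alternatives. Cardiomyocyte markers fell in 20 of 22 cases with none higher at 12 months (adjusted p = 1.17e-16, and adjusted p = 0.107 with an estimated correlation). The counts at 24 months were the same (adjusted p = 3.49e-17, and adjusted p = 0.116 with an estimated correlation). Endothelial markers fell in 16 and rose in 2 of 18 cases at 12 months (adjusted p = 8.62e-24, and adjusted p = 0.105 with an estimated correlation), and as many did at 24 months (adjusted p = 6.09e-23, and adjusted p = 0.0787 with an estimated correlation). Both lists had the same counts adjusted over the list alone.

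The comparison of 24 with 3 months asked what ageing adds to adult fibroblasts. Mitosis genes and most replication genes fell, most p53 targets and secreted inflammatory factors rose, and 15 of 28 collagens fell. Every one of 38 mitosis genes was lower (median -0.77, adjusted p = 5.04e-73, and adjusted p = 0.0887 with an estimated correlation). Mki67 went from 279 ± 8.0 to 147 ± 13 CPM (-0.92 ± 0.05), and topoisomerase Top2a changed by -0.86 ± 0.06 and the centromere protein Cenpf by -0.98 ± 0.07. Replication genes fell in 34 of 36 cases with none higher (median -0.63, adjusted p = 1.62e-32, and adjusted p = 0.106 with an estimated correlation), such as the helicase subunit Mcm5 (-0.69 ± 0.07). Of 23 p53 target genes 19 rose and none fell (adjusted p = 2.62e-16, and adjusted p = 0.0887 with an estimated correlation). This rise starts from the lowest age and was not a steady course. The list's mean centred log2 CPM was 0.287 and 0.252 in neonatal libraries and -0.385 and -0.365 at 3 months. It was 0.121 and 0.112 at 12 months and -0.059 and 0.037 at 24 months, below neonatal and 12 months. Cdkn1a went from 349 ± 2.6 to 541 ± 14 CPM (0.63 ± 0.04), Mdm2 rose by 0.46 ± 0.05 and Eda2r by 0.63 ± 0.06. Trp53 itself was at 111 CPM at both ages (0.01 ± 0.05, adjusted p = 0.96). The inhibitor Cdkn2b rose (0.51 ± 0.14, adjusted p = 0.00858), and Cdkn2a was at 0.69 ± 0.28 (adjusted p = 0.0846). Cdkn1b (-0.25 ± 0.06) and Cdkn2d (-0.37 ± 0.11) fell. As a list the 7 inhibitors of cyclin-dependent kinases (CDK) did not pass, with 2 higher and 2 lower (3 and 3 adjusted over the list alone), a median of -0.09, a mean of 0.06 and a test pointing up (adjusted p = 0.329). That test pointed down with no filter on low counts (adjusted p = 0.978), and fry called the list (adjusted p = 0.028), the highest and the lowest of its alternatives. Adjusted over the list alone, all 36 replication genes fell, and the mitosis and p53 target counts were the same. Cdkn2b did not pass without 3-month replicate 2 (0.43, adjusted p = 0.1), without 24-month replicate 2 (0.48, adjusted p = 0.0632) or with DESeq2 (0.52, adjusted p = 0.0953), with adjusted p from 0.00673 to 0.1. Cdkn1b did not pass without 24-month replicate 2 (-0.21, adjusted p = 0.0587), with 0.00187 its lowest. Cdkn2d did not pass without 3-month replicate 2 (-0.28, adjusted p = 0.229), without 24-month replicate 2 (-0.27, adjusted p = 0.241) or with DESeq2 (-0.36, adjusted p = 0.19), with 0.0191 its lowest. Cdkn2a passed without 3-month replicate 2 (1.20, adjusted p = 0.0154, the lowest of its alternatives, with 0.631 the highest).

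Of 40 senescence-associated secretory factors 26 rose and 6 fell at 24 against 3 months (median 0.47, adjusted p = 5.51e-17), and of 23 chemokines 15 rose and 2 fell (median 0.55, adjusted p = 5.04e-15). Adjusted over the list alone these were 28 and 7, and 17 and 2, and these 2 lists were those that also passed with an estimated correlation. The 2 lists share chemokine genes such as Ccl2, Ccl7 and Cxcl5, so their calls are not separate results. Cxcl14 went from 24.8 ± 0.85 to 92.6 ± 2.4 CPM (1.90 ± 0.07). Ccl6 rose by 1.14 ± 0.06, the protease Mmp12 by 1.13 ± 0.07, the insulin-like growth factor binding protein Igfbp3 by 1.15 ± 0.06 and the metalloprotease inhibitor Timp1 by 0.75 ± 0.04, whereas Igfbp2 fell (-4.04 ± 0.22). The cytokine Il6 rose by 0.41 ± 0.05. Macrophage markers moved with these lists: 12 of 21 rose and none fell (adjusted p = 1.64e-08, and adjusted p = 0.154 with an estimated correlation), including lysozyme Lyz2 (0.70 ± 0.06), with 14 higher adjusted over the list alone. Prostaglandin pathway genes rose in 8 of 13 cases with none lower (adjusted p = 5.66e-05, and adjusted p = 0.0887 with an estimated correlation; 9 adjusted over the list alone). Ptgs2, the inducible cyclooxygenase, rose by 0.73 ± 0.08. Glycolysis genes rose in 17 of 19 cases with none lower (adjusted p = 1.62e-26, and adjusted p = 0.101 with an estimated correlation; the same counts adjusted over the list alone), with lactate dehydrogenase Ldha at 0.61 ± 0.05.

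Downward, 15 of 28 collagens fell and none rose at 24 against 3 months (adjusted p = 2.62e-12, and adjusted p = 0.121 with an estimated correlation; 16 adjusted over the list alone), with Col11a1 at -3.43 ± 0.10 and Col1a1 at -0.27 ± 0.04. Non-collagen matrix genes did not pass as a list, with 13 higher and 15 lower of 42 (15 and 15 adjusted over the list alone), a median of 0.03, a mean of -0.05 and a test pointing down (adjusted p = 0.48). The test pointed up without 24-month replicate 1 (adjusted p = 0.948) and with no filter on low counts (adjusted p = 0.858), within a range of 0.102 to 0.948. Among its members elastin, Eln, fell from 296 ± 19 to 58.1 ± 1.6 CPM (-2.35 ± 0.06) and fibrillin Fbn2 by -2.45 ± 0.11. Ltbp2, a binding protein of elastic fibres, rose from 60 ± 1.1 to 221 ± 2.2 CPM (1.88 ± 0.05). Interferon response genes fell in 25 of 38 cases and rose in 1 (adjusted p = 3.23e-12, and adjusted p = 0.17 with an estimated correlation; 26 and 2 adjusted over the list alone), such as Ifit3 (-0.82 ± 0.08). Imprinted genes fell in 11 and rose in 5 of 26 cases (adjusted p = 3.78e-07, and adjusted p = 0.101 with an estimated correlation; 13 and 5 adjusted over the list alone), with the placental amino acid transporter Slc38a4 at -3.73 ± 0.30. Other leading rises were Xist (10.74 ± 0.09), the neuropeptide Y receptor Npy1r (3.33 ± 0.17) and cardiac actin Actc1 (1.92 ± 0.31). Next were the receptor Gpr35 (1.90 ± 0.13) and myelin basic protein Mbp (1.78 ± 0.17). Then came Tmem132e (1.76 ± 0.16), Ric3 (1.75 ± 0.15) and Mybpc3, a sarcomere protein (1.74 ± 0.44). Mybpc3 had only 15 counts over the 3-month libraries. Other leading falls were Nrk (-5.14 ± 0.24), the guidance receptor Robo2 (-3.29 ± 0.31) and the growth factor Ptn (-2.31 ± 0.24), with count ratios of 10.8 (95% counting interval 1.57 to 465) for Lamc3 and 5.57 (1.61 to 29.7) for Gap43. Robo2 was at -4.05 without 24-month replicate 2. The fall of Lamc3 did not pass without 3-month replicate 1 (adjusted p = 0.173), without 24-month replicate 1 (ratio 5.37, 0.781 to 231, adjusted p = 0.195) or with DESeq2 (adjusted p = 0.143), and 0.0253 was its lowest. That of Gap43 did not pass without 3-month replicate 2 (adjusted p = 0.161), without 24-month replicate 2 (ratio 2.80, 0.811 to 14.9, adjusted p = 0.266) or with DESeq2 (adjusted p = 0.0564), and 0.00675 was its lowest. Cardiomyocyte markers rose in 8 of 22 cases with none lower (adjusted p = 2.29e-05, and adjusted p = 0.264 with an estimated correlation; 11 adjusted over the list alone). Endothelial markers fell in 14 of 18 with none higher (adjusted p = 4.18e-11, and adjusted p = 0.17 with an estimated correlation; 16 adjusted over the list alone).

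In total 3014 genes differed between 24 and 3 months, 1450 higher and 1564 lower, and 461 of them at least 2-fold (215 higher, 246 lower). Of 39 lists 26 moved, 15 up and 11 down, and an estimated correlation left 2. With upper-quartile scaling the split was 1549 higher and 1426 lower, and DESeq2 called 1898 genes. Between these ages Xist and the Y-linked genes changed as well, with Ddx3y at -1.66 ± 0.05, beside every list described.

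The step from 3 to 12 months, set within adult life, asked whether change begins before old age. All interferon response genes and most collagens and mitosis genes fell, and most ribosomal protein, respiratory chain and p53 target genes rose. With an estimated correlation 0 of 39 lists passed in limma camera, 10 had an unadjusted p under 0.05, and fry, which tests a list on its own, called 32. All 38 interferon response genes were lower at 12 months (median -1.25, adjusted p = 3.82e-85, and adjusted p = 0.0501 with an estimated correlation). The interferon regulator Irf7 went from 92.1 ± 3.8 to 30.4 ± 2.5 CPM (-1.60 ± 0.07) and Ifit3 from 269 ± 36 to 80.7 ± 12 CPM (-1.73 ± 0.08). Mitosis genes fell in 37 of 38 cases with none higher (median -0.59, adjusted p = 2.66e-28, and adjusted p = 0.18 with an estimated correlation), Mki67 by -0.72 ± 0.05. Of 23 p53 targets 19 rose and 1 fell (adjusted p = 7.6e-18, and adjusted p = 0.14 with an estimated correlation), Cdkn1a by 0.72 ± 0.04. Collagens fell in 20 of 28 cases with none higher (adjusted p = 1.01e-20, and adjusted p = 0.14 with an estimated correlation), Col3a1 from 13500 ± 160 to 6950 ± 430 CPM (-0.95 ± 0.04) and Col14a1 by -2.13 ± 0.07. Ribosomal protein genes rose in 74 of 81 cases and fell in 1, by a median of 0.28 (adjusted p = 1.12e-22, and adjusted p = 0.25 with an estimated correlation). Of 49 nuclear respiratory chain genes 28 rose with none lower (adjusted p = 2.53e-06, and adjusted p = 0.272 with an estimated correlation). Adjusted over the list alone, 20 p53 targets, 75 ribosomal protein genes and 32 respiratory chain genes rose, and the other counts did not change.

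Among called genes with a mean of at least 5 CPM over the 8 libraries, the largest rise from 3 to 12 months was in Slc7a11, the cystine importer that feeds glutathione synthesis, from 9.38 ± 1.4 to 40.8 ± 9.0 CPM (2.13 ± 0.13). It was followed by Mybpc3 (2.09 ± 0.42), Ccl11 (2.00 ± 0.12), the p53 target Perp (1.97 ± 0.18) and Actc1 (1.89 ± 0.32). Mybpc3 rests on few reads, with 15 counts over the 3-month libraries. The largest falls under that limit were in Nrk (-3.62 ± 0.20), Igfbp5 (-3.29 ± 0.13), Fbn2 (-3.25 ± 0.13) and Robo2 (-3.21 ± 0.32). Acan fell at least 5.52-fold, from 19 counts at 3 months to 0 at 12 months, a bound that gives it no rank. The limit of 5 CPM includes the neonatal libraries, where Acan had 1132 counts. Without 12-month replicate 1, Mybpc3 was at 1.35 (adjusted p = 0.0414) and Robo2 at -4.28, and without 12-month replicate 2 Robo2 was at -2.53. In total 4680 genes passed, 2130 higher and 2550 lower, with 705 at least 2-fold (229 higher, 476 lower), and 26 of 39 lists moved, 9 up and 17 down. Upper-quartile scaling gave 2638 higher and 2154 lower, and DESeq2 called 3091 genes. Cardiomyocyte markers rose in 14 of 22 cases with none lower (adjusted p = 4.55e-06, and adjusted p = 0.25 with an estimated correlation; 17 adjusted over the list alone). Endothelial markers fell in 15 of 18 with none higher (adjusted p = 1.9e-06, and adjusted p = 0.25 with an estimated correlation; 16 adjusted over the list alone). Macrophage markers rose in 9 and fell in 2 of 21 cases (adjusted p = 0.000449, and adjusted p = 0.266 with an estimated correlation; 10 and 2 adjusted over the list alone).

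From 12 to 24 months, the step from middle to old age, most interferon response, MHC class I, complement and non-collagen matrix genes rose, most ribosomal protein genes fell, and 9 of 38 mitosis genes fell further. With an estimated correlation 0 of 39 lists passed in camera, 13 had an unadjusted p under 0.05, and fry called 21. This comparison and that of 12 with 3 months share the 12-month libraries, so opposite changes in them are not independent. Interferon response genes rose in 35 of 38 cases with none lower (median 0.75, adjusted p = 8.74e-65, and adjusted p = 0.0783 with an estimated correlation), including Ifi44, from 8.21 ± 3.1 to 42.3 ± 1.6 CPM (2.34 ± 0.13), and Irf7 (1.35 ± 0.07). All 16 MHC class I genes rose (adjusted p = 9.12e-21, and adjusted p = 0.0989 with an estimated correlation). Of 20 complement genes 13 rose with none lower (adjusted p = 6.3e-20, and adjusted p = 0.0783 with an estimated correlation). Ribosomal protein genes fell in 76 of 81 cases with none higher (median -0.28, adjusted p = 9.89e-35, and adjusted p = 0.219 with an estimated correlation). Non-collagen matrix genes rose in 27 and fell in 7 of 42 cases (adjusted p = 1.8e-19, and adjusted p = 0.0989 with an estimated correlation), such as the adhesive glycoprotein Tnc (0.64 ± 0.04). Glycolysis genes rose in 15 of 19 cases with none lower (adjusted p = 3.85e-17, and adjusted p = 0.133 with an estimated correlation), led by the lactate exporter Slc16a3 (1.77 ± 0.09). Secretory factors rose in 18 and fell in 8 of 40 cases (adjusted p = 2.43e-06, and adjusted p = 0.0783 with an estimated correlation), with Igfbp3 at 1.54 ± 0.07 and Mmp3 at 0.77 ± 0.04. Mitosis genes fell further in 9 of 38 cases with none higher (adjusted p = 8.86e-05, and adjusted p = 0.564 with an estimated correlation and 0.198 with fry). Adjusted over the list alone, 14 complement genes rose, 78 ribosomal protein genes fell, 29 matrix genes, 16 glycolysis genes and 19 secretory factors rose, 9 secretory factors fell and 16 mitosis genes fell, and the other counts did not change.

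Under the same limit of 5 CPM, the largest rises from 12 to 24 months were in Xist (11.05 ± 0.10), Npy1r (2.66 ± 0.16) and Igfbp5 (2.57 ± 0.14). Acan rose at least 2.36-fold, from 0 counts at 12 months to 8 at 24 months, a bound that gives it no rank. Without 24-month replicate 1 the bound for Acan was 1.19-fold. The largest falls under that limit were in Igfbp2 (-2.49 ± 0.27), Slc7a11 (-2.16 ± 0.13) and Slc38a4 (-1.87 ± 0.42), with count ratios of 12.4 (95% counting interval 1.80 to 534) for Lamc3 and 5.64 (1.60 to 30.4) for Gap43. In total 3094 genes passed, 1769 higher and 1325 lower, with 311 at least 2-fold (232 higher, 79 lower), and 23 of 39 lists moved, 17 up and 6 down. Upper-quartile scaling gave 1530 higher and 1671 lower, DESeq2 called 1971 genes, and 1814 and 2056 passed without 12-month replicate 2 and without 24-month replicate 2. Lamc3 did not pass without 12-month replicate 1 (adjusted p = 0.0779), without 24-month replicate 1 (ratio 6.17, 0.896 to 265, adjusted p = 0.136) or with DESeq2 (adjusted p = 0.102), with 0.0145 its lowest. Gap43 did not pass without 12-month replicate 1 or 2 (adjusted p = 0.0738 and 0.106), without 24-month replicate 2 (ratio 2.84, 0.803 to 15.3, adjusted p = 0.259) or with DESeq2 (adjusted p = 0.0537), with 0.00717 its lowest. Acan did not pass without 12-month replicate 1 or 2 (adjusted p = 0.1 and 0.152) or without 24-month replicate 1 (adjusted p = 0.192), with 0.0147 its lowest. Macrophage markers rose in 4 and fell in 1 of 21 cases (adjusted p = 0.298; the same counts adjusted over the list alone). The list passed with no filter on low counts (adjusted p = 0.0396, the lowest of its alternatives).

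**Figure D4:**
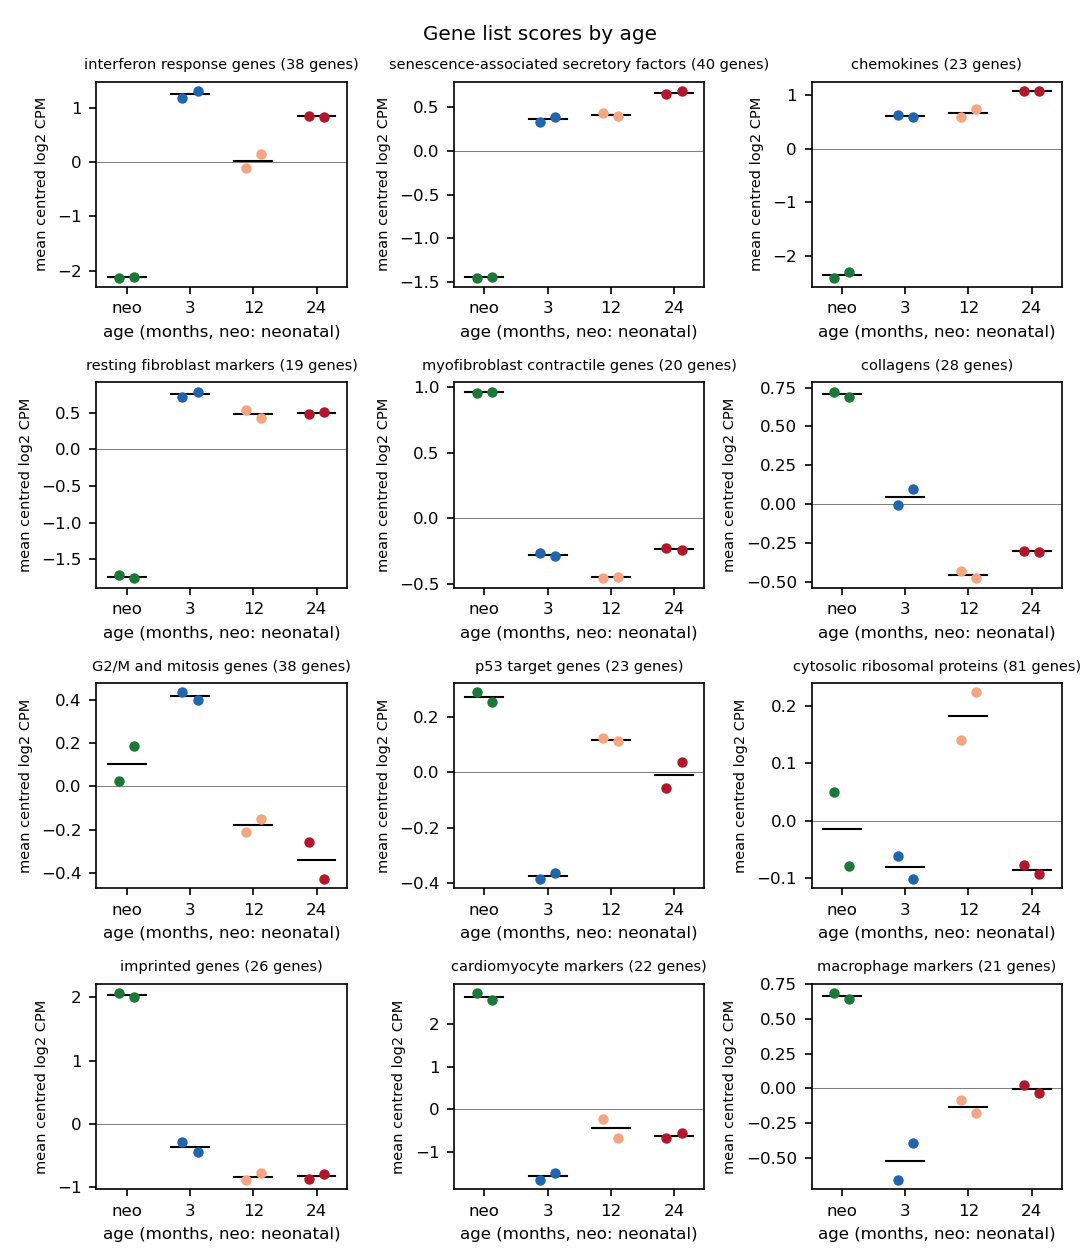
Score of 12 gene lists in each library by age: the mean over the list's genes of log2 CPM centred on each gene's mean over the 8 libraries; points are libraries and bars are means of 2, and each panel has its own linear axis. Interferon response genes score -2.127 and -2.118 in neonatal libraries, 1.194 and 1.318 at 3 months, -0.114 and 0.149 at 12 months, and 0.862 and 0.837 at 24 months.

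Whether genes that change as the heart matures go on in the same direction late in life was asked by crossing 3 months against neonatal with 24 against 12 months, which share no library. Of 2282 genes called in both, 1106 rose in both, where independent lists would share 495.1, and 440 fell in both, where they would share 322.9. Opposite courses were taken by 385 that rose then fell (370.8 for independent lists) and 351 that fell then rose (431.1). The direction was the same for 67.7% (95% Clopper-Pearson interval 65.8 to 69.7, counting error only). The step from 3 to 12 months is outside this crossing, so a late rise that follows a fall in that step also counts as the same direction. Interferon response genes took such a course, with median log2 fold changes of 3.63 from neonatal to 3 months, -1.25 to 12 months and 0.75 to 24 months. Across all 16466 genes the 2 log2 fold changes had Pearson r 0.13 and Spearman rho 0.12, and genes are not independent replicates. The median of the Y-linked genes also differed in both comparisons, and Xist fell in the first and rose in the second.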

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

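Tests of loss of Y-linked expression, of immune cells and of each of the 3 other heart cell types were chosen after their results were seen. So were those of sex as the cause of the mitosis, p53 target, collagen and interferon changes. Predictions for cells of both sexes, scaling, batches and a lower fibroblast share were recorded before those tests. Their wording names the patterns they address, so these patterns had been seen.

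Sex-linked transcripts stood out because they carry a signal outside the comparisons of the report, in genes that no comparison was about. Xist averaged 1280 CPM in the neonatal and 804 CPM in the 24-month libraries, and the median of the Y-linked genes was 20.2% and 30.6% of its 3-month level in these ages. Loss of Y-linked expression in male cells with age is argued against as the only cause, since the lower Xist value at 24 months was 775 CPM. Whether male cells lost Y-linked expression beside female cells was not tested. For the step from 3 to 12 months, sex makeup as the cause of lower mitosis genes, higher p53 targets and lower collagens is argued against. Xist stayed below 1 CPM at both ages, and 37, 19 and 20 members moved that way. This does not decide the cause of the changes at 24 against 3 months, where the sex-linked transcripts differ. The pattern is consistent with cells of both sexes in neonatal and 24-month cultures and of males at 3 and 12 months, because 4 genes that escape X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) were all higher at 24 than at 3 months, with a median log2 fold change of 0.41. Sex and age thus remain mixed in every comparison except 12 with 3 months. There 26 of 39 lists moved with the preset correlation between genes and 0 with an estimated one. How much of the changes in the other comparisons goes with sex was not separated from age.

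Interferon response genes were highest at 3 months, at scores of 1.194 and 1.318. Scaling is argued against, since the list's median fell from 3 to 12 months under all 3 scalings, the highest being -1.21, and sex makeup is argued against for that step, where the Y-linked median was -0.04. A lower share of macrophages at 12 months is argued against as the source, since the macrophage markers had a median log2 fold change of 0.52 from 3 to 12 months. The interferon genes fell over that step. Other immune cells were not tested, as the lymphocyte markers had 1 tested gene. Interferon gene levels within macrophages were not tested either. A difference between culture or library batches cannot be told apart from age, since the labels give 0 ages with more than 1 batch. Age itself may be the source, as a hypothesis that these libraries leave untested.

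Markers of other heart cells were higher in the neonatal libraries than at 3 months. Cardiomyocyte markers (median -4.35, 22 genes) and macrophage markers (median -1.38, 21 genes) fell by different amounts. A permutation that treats genes as independent gave a two-sided p of 1e-05, the smallest 100000 permutations can give. Whether one lower fibroblast share with the same mix of other cells was the cause cannot be told from this. Expression of some markers by the fibroblasts themselves would also make the falls differ. Cardiomyocytes, endothelial cells and epicardial or mesothelial cells in the neonatal cultures cannot be told apart from expression by the fibroblasts themselves. The shares of their tested markers at least 2-fold higher there were 100%, 72.2% and 91.7%, but these markers make up the pattern, so their shares decide nothing between the 2. Tnnt2 was at 764 CPM in neonatal cells, and 5 of 22, 18 of 18 and 4 of 12 markers were still at 1 CPM or more in both 3-month libraries.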

How the results depend on the processing

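The runs with autosomal genes only and with the neonatal or 24-month libraries left out were chosen after seeing the data. Of 336 alternative values of the main results, 312 kept their direction and their side of the threshold, or stayed within 1.5-fold of the count. A minimum change of 2-fold, which asks more of each gene, left 3101, 3296 and 3375 genes for 3, 12 and 24 months against neonatal, 705 for 12 against 3 months, 311 for 24 against 12 months and 461 for 24 against 3 months. An estimated correlation left 7, 6, 8, 0, 0 and 2 lists in the same order, and in each of the 46 described lists that lost their call it gave the highest adjusted p of all alternatives. DESeq2 called 3091 genes for 12 against 3 months, 1971 for 24 against 12 months and 1898 for 24 against 3 months. It gave Nr4a3 0.92 for 3 months against neonatal and 0.94 for 12 against 3 months, no longer past the threshold (adjusted p = 0.0688 and 0.0506, within ranges of 0.00231 to 0.277 and 0.000269 to 0.0945); the cause of these lower DESeq2 calls was not tested. With each library left out in turn, Nr4a3 ranged from 0.47 to 1.46 and from 0.73 to 1.12 in these comparisons, the genes called for 24 against 12 months from 1814 to 3050, and the share with the same later direction from 67.2 to 71.8%. Each of these runs has 1 library fewer, and what else lowered the count or raised the share was not tested. The stricter filter removed Nr4a3, which has no value there. A replicate block called 2913 genes for 24 against 12 months and 2844 for 24 against 3 months, and replicate numbers did not pair the libraries (correlations of deviations from -0.039 to 0.032).

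For named genes 2694 of 2743 alternative values kept their direction and call, 45 no longer passed, 2 passed anew and 2 turned. Trp53 at 24 against 3 months, not called, turned from 0.01 to -0.03 without 3-month replicate 2 (adjusted p = 0.845) and ranged up to 0.05 over the libraries left out; the cause was not tested. Nr4a1 at 24 months against neonatal, not called, ranged from -0.38 to 0.06 over the libraries left out. For the lists described, 801 of 810 values outside the estimated correlation and fry kept their direction and call. The non-collagen matrix genes at 24 against 3 months, not called, turned direction with no filter on low counts (adjusted p = 0.858) and without 24-month replicate 1, with adjusted p from 0.102 to 0.948 over the libraries left out. The CDK inhibitors in that comparison, not called, turned with no filter (adjusted p = 0.978); the causes were not tested. Autosomal genes only, and leaving out the neonatal or the 24-month libraries, moved 0 of the main counts by more than 1.5-fold. X-linked genes were 3.33% of the genes tested, so the autosomal run could hardly move a count and does not test an effect of sex on autosomal genes. The other runs covered only comparisons that do not use the libraries left out. Depth limits low genes most: 3 counts are 0.134 to 0.174 CPM per library, and Nr4a3 rests on 17 to 98 counts per library.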

Other observations

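The glutathione theme was chosen after its enrichment was seen, and the 2 comparisons it joins share the 12-month libraries, so opposite changes in them are not independent. Among genes at least 2-fold higher at 12 than at 3 months, muscle terms had the lowest adjusted p. They were ventricular cardiac muscle tissue morphogenesis (adjusted p = 0.000401), sarcomere organization (adjusted p = 0.000581) and muscle contraction (adjusted p = 0.00156). Glutathione metabolic process came next, with 7 of its 52 tested genes where 0.707 would fall by chance (adjusted p = 0.00318). Of the 7, Mdga2 (0 and 0.264 CPM at 3 and 12 months) and Gsta4 (0.484 and 2.66 CPM) were at low levels. The 52 genes count pseudogenes such as Gstp-ps and Gpx4-ps2 as separate members. Of the 52 genes 23 rose and 1 fell from 3 to 12 months, the fall being that of the secreted peroxidase Gpx3 (-1.08 ± 0.05). From 12 to 24 months 17 fell and 4 rose, and 16 genes rose and then fell. The cystine importer Slc7a11 went from 9.38 to 40.8 and back to 9.19 CPM (2.13 ± 0.13, then -2.16 ± 0.13). Both subunits of the rate-limiting synthesis enzyme followed, Gclm by 1.15 ± 0.05 and then -0.84 ± 0.05, and Gclc by 0.74 ± 0.05 and then -0.63 ± 0.05. Among the glutathione transferases Gsta3 moved by 1.16 ± 0.05 and -0.98 ± 0.05, Gsto1 by 1.21 ± 0.08 and -0.86 ± 0.07, and Gstp1 by 1.04 ± 0.08 and -0.81 ± 0.08.

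Terms enriched between neonatal and 3 months extended the lists of the report. Among genes at least 2-fold higher at 3 months, response to bacterium held 62 of its 135 tested genes where 12.6 would fall by chance (adjusted p = 1.44e-25). Among genes at least 2-fold lower, sarcomere organization held 23 of 37 (3.46 by chance, adjusted p = 6.14e-12), and axon guidance, which names genes that steer growing nerve fibres, held 34 of 133 (12.4 by chance, adjusted p = 1.56e-05).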
